A study of Homo sapiens with 30 samples.

How the data were processed

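The samples are A549 cells treated for 24 h with ethanol extracts of Samul-tang, Sagunja-tang, Palmul-tang or Sibjeondaebo-tang at 20, 100 or 500 µg/mL, or with vehicle. Per the labels, total RNA with an integrity number above 7 went into stranded libraries that were sequenced as 100 bp pairs on an MGI instrument. The authors checked reads with FastQC 0.11.9, trimmed them with Trim Galore 0.6.5, aligned them to GRCh38 with STAR 2.7.3a and quantified genes with RSEM 1.3.3. The annotation release and the strand setting of the counting are not stated. The deposited values are expected counts per gene from RSEM, in which a read shared by several genes is divided among them, and between 8.50% and 9.82% of the values per library are not whole. They were rounded to whole numbers before testing. The table holds 60675 gene rows. It also holds 240 columns of other samples that were not used here, and 30 columns were matched to samples by the library codes in the labels.

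Samples were grouped by formula and dose as the labels give them, in 13 groups of 1 to 3 libraries. Totals ran from 23986637 to 35159898 counts per library. The precision of each value is given by the SD over replicate libraries, and values of Sagunja-tang have no replicate. Replicate numbers were tested as pairs: the correlation of deviations from the group mean between libraries of the same number had a median of 0.014 over 63 pairs (from -0.10 to 0.089), against -0.148 to 0.112 between other libraries. The numbers were therefore not used as pairs, and a fit with them as a block is an alternative.

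Genes were kept by filterByExpr with the groups, which left 17701, and libraries were scaled by TMM, with factors from 0.923 to 1.0515. One model with a mean per group over all 30 libraries was fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, glmQLFTest), with 17 residual degrees of freedom and a common dispersion of 0.00246. The spread is shared over all groups. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, with a threshold of 0.05. SEs of log2 changes are the change divided by the square root of its F statistic. The dose step is the contrast of high minus low dose divided by 2, which is the least-squares slope per 5-fold dose. It equals the change in each step only where the change was even. CPM values use the TMM-scaled library sizes.

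A set of 28 gene lists with 534 genes, of which 492 were tested, was written before the data were examined, as were the comparisons and the rule for naming genes. Lists with at least 5 tested genes, 27 of them, were tested with camera from limma 3.58.1 with a preset correlation of 0.01 and, beside it, with a correlation estimated for each list. Both were adjusted over the lists. fry was run as well, and its values test only whether the genes of a list move. Counts of list members past the threshold are given over all genes and adjusted over the list alone.

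Genes named as large changes in a high-dose comparison or a dose step were among the 8 largest in each direction that passed the threshold, with a mean log2 CPM of at least 2, a symbol, and no overlap between the libraries of both groups. For the medium and low doses and for Sagunja-tang the 3 largest in each direction were eligible. From each list up to 4 members with the smallest adjusted p were eligible. Members of a fixed list outside this rule are named only with their values. STC1, ID2 and the genes of the interaction were chosen after their values were seen.

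The test was tested on simulated data drawn with a single mean per gene over all 30 libraries and the fitted dispersions. Log2 changes of 0.5, 1 or 2 were put into 200 genes of the changed group, and 17501 genes were left unchanged. In the real comparisons with vehicle 2448 to 7395 genes passed, so the shares below need not hold there. For 3 against 3 libraries, 97% of genes raised by 2, 63.6% raised by 1, 66.7% raised by 0.5, 85.3% lowered by 2, 73.5% lowered by 1 and 57.6% lowered by 0.5 were recovered. For the 2 libraries of Samul-tang against 3, the lowest shares were 33.3% of genes lowered by 0.5 and 54.5% raised by 0.5. In the first case 5.73% of the calls were genes left unchanged. For a lone library against 3 the unchanged share was 4.46%. That library was drawn with the same spread as the others, so this share cannot test whether the libraries of Sagunja-tang vary likewise.

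Alternatives were DESeq2 1.42.0 (Wald test), RLE size factors, no filter on low counts, a fit to only the groups compared, the replicate number as a block, leaving out each library in turn, and the estimated correlation for lists. The low dose as the reference, fits without the vehicle or without the high dose of Sibjeondaebo-tang, and counts thinned to the smallest total of 23986616 were added after the data were seen. For groups of 3, every one of the 10 splits of the 6 libraries was fitted in place of the real one. Gene length, GC content, gene class, overlaps and retained-intron isoforms were taken from GENCODE v29 on GRCh38, which holds 94.03% of the gene rows. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.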

Results

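RNA abundance was measured in A549 cells, a human lung carcinoma line, after 24 h with an ethanol extract of 1 of 4 Korean tonifying formulas or with vehicle. Each formula was given at a low dose of 20 µg/mL, a medium dose of 100 µg/mL and a high dose of 500 µg/mL. Palmul-tang and Sibjeondaebo-tang had 3 libraries per dose, Samul-tang had 2 per dose, Sagunja-tang had 1 per dose, and the vehicle had 3, which makes 30 libraries in 13 groups. The labels number the Samul-tang libraries as replicates 2 and 3 and the Sagunja-tang libraries as replicate 3, and no other replicate of these formulas was analysed here. Palmul-tang combines the herbs of Sagunja-tang and Samul-tang, and Sibjeondaebo-tang holds the herbs of Palmul-tang with others added. The vehicle was 0.1% DMSO in the sample labels and 2% in the text of the series, and the difference could not be settled from the counts. The wortmannin treatment that the series text mentions was not analysed here.

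The totals ran from 23986637 to 35159898 expected counts per library, with a median of 32383996, and the smallest total was that of vehicle replicate 3. Of 60675 gene rows, 33568 held a count in some library and 17701 were abundant enough to test. Replicates of a group correlated at 0.990 to 0.993 across genes. Gene-level variation between replicates was small, with a biological coefficient of variation of 0.0496. The titles number the replicates and do not state whether they were separate cultures. The SDs and p-values therefore describe the spread between these libraries, which may be smaller than that between repeated experiments. Values below are CPM, counts scaled to the library size, with the SD over libraries, and coordinates are on GRCh38.

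The first principal component held 14.67% of the variance and separated the 3 libraries of the high dose of Sibjeondaebo-tang, at 39.85 to 48.09, from the other 27, at -14.95 to 5.94. The second held 10.03% and separated the 3 vehicle libraries, at 30.82 to 43.06, from every extract library, at -11.58 to 6.10. The titles place all 30 libraries in 1 batch, E. The library codes nevertheless begin with E1 for the vehicle and with 14 or 15 for the extracts, and what these prefixes stand for is not stated. If they mark separate preparations, these coincide with the difference between vehicle and extract. For this reason the response to dose within a formula, which uses no vehicle library, is given first.

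**Figure D1:**
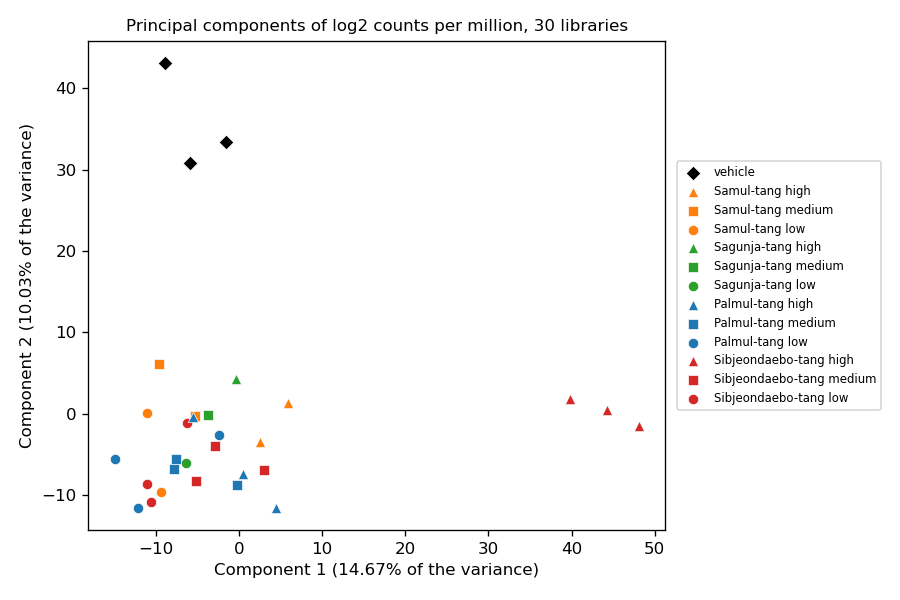
Each point is 1 of the 30 libraries, placed by its score on component 1 (horizontal, 14.67% of the variance) and component 2 (vertical, 10.03%) of log2 CPM, with the colour giving the formula and the shape the dose. The high dose of Sibjeondaebo-tang lies at 39.85 to 48.09 on the horizontal axis and the vehicle at 30.82 to 43.06 on the vertical axis, each away from all other libraries.

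The dose step asks which transcripts followed the dose of a formula. It is the log2 change from the low to the high dose divided by 2, an average per 5-fold increase of dose. It uses no medium-dose library, so it does not show whether the change was even over the 2 steps. In Sibjeondaebo-tang 6805 genes passed the threshold of an adjusted p under 0.05, of which 3276 rose and 3529 fell with dose. Which direction held more genes depended on the processing: 3522 rose and 3097 fell with no filter on low counts, and 3091 and 2931 with DESeq2. It also turned without Sibjeondaebo-tang high replicate 1 (3119 and 2620), without Sibjeondaebo-tang high replicate 2 (3434 and 2761) and without Sibjeondaebo-tang high replicate 3 (3425 and 2935). In Palmul-tang 615 passed, with 258 rising and 357 falling, and the count was 351 without Palmul-tang high replicate 1 and 371 without Palmul-tang low replicate 3. In Samul-tang 238 passed, with 107 rising and 131 falling (169 and 152 with DESeq2), over 2 libraries per dose. This count was 58 without Samul-tang high replicate 2, 149 without Samul-tang low replicate 2, 106 without Samul-tang high replicate 3 and 49 without Samul-tang low replicate 3. It was higher, at 464 with no filter, 373 with the replicate block and 488 with only the groups compared in the fit. Between the medium and high doses 152 genes passed in Palmul-tang, 5408 in Sibjeondaebo-tang and 60 in Samul-tang. By contrast, edgeR called 1 gene between the medium and low doses of Palmul-tang (741 at an unadjusted p under 0.05), 2 in Sibjeondaebo-tang (1108 unadjusted) and 0 in Samul-tang (988 unadjusted). DESeq2 was not run on the medium against the low dose.

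Transcripts of aryl hydrocarbon receptor (AhR) targets rose with the dose of all 3 formulas. CYP1B1 (ENSG00000138061, chromosome 2, 38066973 to 38109902, whose exons overlap those of RMDN2-AS1 on the same strand and of CYP1B1-AS1 and RMDN2 on the other) stood at 123 ± 1.77 CPM at the low dose of Sibjeondaebo-tang and 228 ± 9.25 at the high dose (n = 3 each). That was a dose step of 0.44 log2 (SE 0.019, adjusted p = 1.18e-17). In Palmul-tang CYP1B1 went from 123 ± 2.96 to 207 ± 3.01 CPM (0.38, SE 0.019, adjusted p = 1.93e-15). In Samul-tang it went from 122 ± 5.88 to 182 ± 0.473 CPM (n = 2 each), a step of 0.29. CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725610) was near the floor at every low dose. It rose from 0.327 ± 0.0506 to 3.01 ± 0.549 CPM with Sibjeondaebo-tang, from 0.280 ± 0.0305 to 3.74 ± 0.727 with Palmul-tang and from 0.185 ± 0.133 to 1.79 ± 0.366 with Samul-tang. ALDH3A1 (ENSG00000108602, chromosome 17, 19737984 to 19748943), far more abundant, rose from 953 ± 63.7 to 1691 ± 43.1 CPM with Sibjeondaebo-tang and from 988 ± 10.7 to 1649 ± 40.7 with Palmul-tang. Of the 9 tested genes on the AhR list, 6 rose and 1 fell in Sibjeondaebo-tang, with the same counts when adjusted over the list alone. In Palmul-tang 6 rose and 0 fell, and 7 rose and 1 fell when adjusted over the list alone. In Samul-tang 4 rose, and 5 rose and 1 fell when adjusted over the list alone. The list as a whole passed in all 3 formulas, with adjusted p = 0.000477, 1.65e-07 and 4.78e-05 with an estimated correlation. The list tests of the dose step of Samul-tang, over 2 libraries per dose, were not planned beforehand. They were not repeated without single libraries or on other splits, unlike those of the other formulas.

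Targets of NRF2, the regulator of the response to oxidants and electrophiles, moved the same way. HMOX1 (ENSG00000100292, chromosome 22, 35380361 to 35394214) rose from 45.4 ± 2.64 to 84.5 ± 4.86 CPM in Sibjeondaebo-tang, a dose step of 0.45 (SE 0.026, adjusted p = 1.49e-14). The corresponding means were 45.1 ± 1.51 and 67.3 ± 1.86 CPM in Palmul-tang (step 0.29) and 43.8 ± 0.623 and 78.2 ± 0.944 in Samul-tang (step 0.42). HMOX1 at all 3 low doses lay below the vehicle, which stood at 53.2 ± 3.89 CPM. At the medium dose of Sibjeondaebo-tang its libraries held 45.54, 49.95 and 49.68 CPM, nearer to the low than to the high dose. GCLM, for the modifier subunit of glutamate-cysteine ligase, rose from 136 ± 7.35 to 184.5 ± 5.28 CPM in Sibjeondaebo-tang and from 133.5 ± 4.78 to 174 ± 0.258 in Palmul-tang. Of 25 NRF2 targets, 18 rose and 2 fell in Sibjeondaebo-tang (20 and 2 adjusted over the list alone). ABCC2 fell there, from 468 ± 20.7 to 347 ± 3.67 CPM. In Palmul-tang 10 rose and 0 fell (15 and 1 adjusted over the list alone), and in Samul-tang 9 rose and 0 fell (10 and 0 adjusted over the list alone). The list passed in each formula, with adjusted p = 0.0127 in Sibjeondaebo-tang, 0.000438 in Palmul-tang and 0.0036 in Samul-tang with an estimated correlation. The list of ATF4 targets and amino acid transport passed in each as well, at 0.0103, 0.000438 and 0.00601. Its member SLC7A5 rose from 964 ± 55.6 to 1517 ± 58.3 CPM in Sibjeondaebo-tang, from 991 ± 58.1 to 1208 ± 38.3 in Palmul-tang and from 961 ± 48.7 to 1299 ± 27.8 in Samul-tang.

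Outside the lists, AQP3, NOTCH3 and EEF1A2 were among the 8 largest rises in both 3-library formulas. AQP3 (ENSG00000165272, chromosome 9, 33441154 to 33447633), a channel for water and glycerol, went from 63.0 ± 1.03 to 110.5 ± 4.78 CPM in Sibjeondaebo-tang and from 61.9 ± 0.926 to 105 ± 3.46 in Palmul-tang. NOTCH3 went from 29.04 ± 1.44 to 48.7 ± 1.93 and from 30.4 ± 3.23 to 45.9 ± 1.59 CPM. In Sibjeondaebo-tang 4 genes passed with a rise of 1 log2 or more per step. Among genes that met the naming rule, the largest fitted rise there was that of SULT1A3, at 0.56. SULT1A3 has a near-identical copy that shares its reads. SULT1A3 no longer passed without Sibjeondaebo-tang high replicate 2 (adjusted p = 0.0699) or without Sibjeondaebo-tang low replicate 3 (0.0693).

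**Figure D2:**
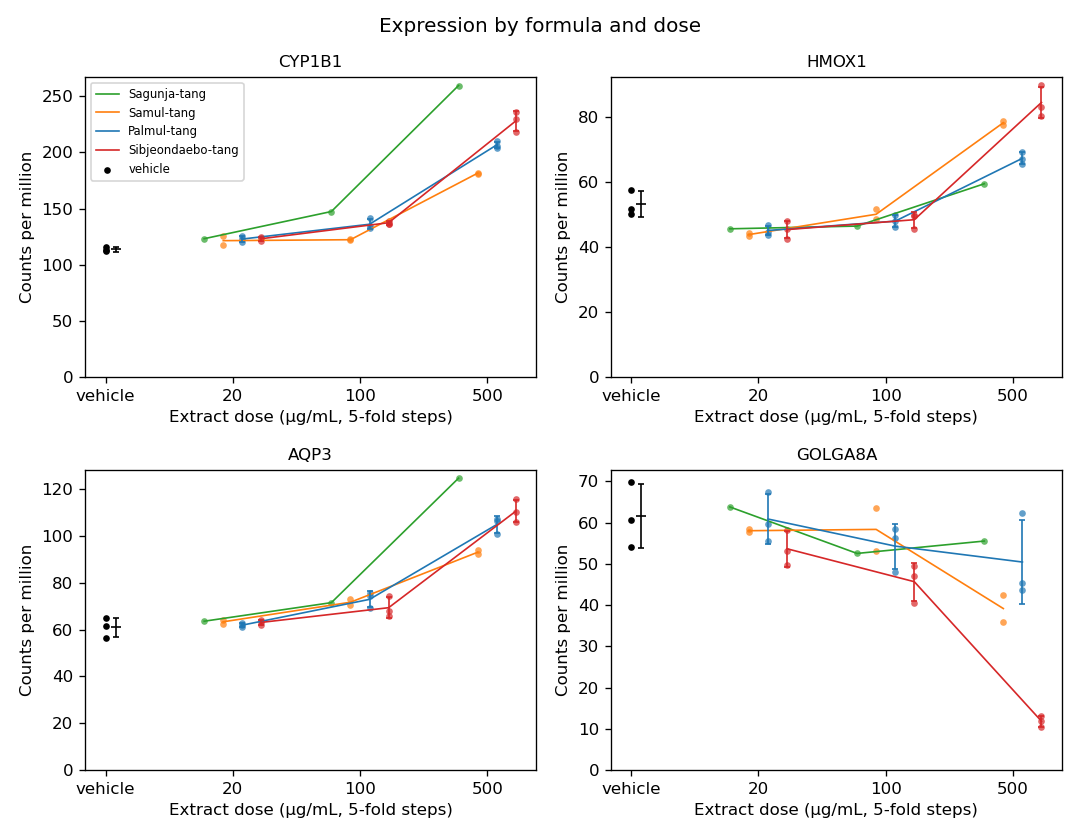
CPM (vertical) of CYP1B1, HMOX1, AQP3 and GOLGA8A against extract dose in µg/mL (horizontal, 5-fold steps), with points for libraries, lines through group means and bars of 1 SD where a group has 3 libraries. CYP1B1 reached 228 and 207 CPM at the high doses of Sibjeondaebo-tang and Palmul-tang, and GOLGA8A fell to 11.8 CPM at the high dose of Sibjeondaebo-tang against 50.4 with Palmul-tang.

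The 8 largest falls in Palmul-tang that met the naming rule were those of APOB, PGC, MUC3A, KNG1, NR4A1, SERPINA1, LEFTY1 and CLDN2. APOB fell from 9.47 ± 0.603 to 4.89 ± 0.567 CPM, PGC from 36.2 ± 3.33 to 20.8 ± 1.3, KNG1 from 19.35 ± 2.21 to 11.3 ± 1.04 and NR4A1 (ENSG00000123358, chromosome 12, 52022832 to 52059507) from 14.5 ± 1.17 to 8.60 ± 0.186. The hepatocyte list, with 6 tested genes, fell in Palmul-tang (adjusted p = 0.00674 with an estimated correlation), with 2 members past the threshold, HP and APOH, over all genes and when adjusted over the list alone. Proliferation genes rose in Palmul-tang: 23 of 29 mitosis genes (26 adjusted over the list alone, list adjusted p = 0.00212 with an estimated correlation) and 10 of 29 DNA replication genes (20 adjusted over the list alone, 0.00828). TOP2A, for example, went from 272 ± 15.8 to 334 ± 13.5 CPM. The same 2 lists rose in Sibjeondaebo-tang under the preset correlation, with 21 mitosis genes up and 4 down (23 and 4 adjusted over the list alone) and 20 replication genes up and 1 down (21 and 1), but did not pass with an estimated correlation (adjusted p = 0.251 and 0.145). Fatty acid synthesis fell in Palmul-tang, with 4 of 11 genes down (7 adjusted over the list alone, 0.0175 with an estimated correlation), as did glucocorticoid receptor targets (2 of 13, or 4 adjusted over the list alone, 0.000598) and FOXO targets (2 of 13, or 3 adjusted over the list alone, 0.00674). Of the 27 lists tested, 17 passed in Palmul-tang with the preset correlation and 9 with the estimated one, and 12 and 3 in Sibjeondaebo-tang. With the preset correlation, wrong splits of the same libraries gave up to 15 lists in Palmul-tang and up to 10 in Sibjeondaebo-tang. A list that passed only with the preset correlation is therefore weak evidence. In Sibjeondaebo-tang 24 of 30 ribosomal protein genes (26 adjusted over the list alone) and 17 of 25 nuclear-encoded respiratory chain genes (18 adjusted over the list alone) rose, by a median of 0.11 and 0.09 log2 per step. Those lists did not pass with an estimated correlation (adjusted p = 0.251 and 0.366).

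In Samul-tang the hypoxia and glycolysis list rose, with 8 of 23 genes up (12 adjusted over the list alone, list adjusted p = 0.00601 with an estimated correlation). As with the other list tests of this dose step, it was not repeated without single libraries. ALDOC went from 15.6 ± 0.167 to 23.6 ± 0.179 CPM and SLC2A1 from 71.55 ± 3.86 to 91.9 ± 3.65 (n = 2 each). NF-kB and inflammatory genes fell, with 3 of 22 down (6 adjusted over the list alone, 0.01 with an estimated correlation). CXCL1 went from 21.4 ± 0.623 to 12.4 ± 0.654 CPM in Samul-tang, from 20.9 ± 2.00 to 13.1 ± 0.768 in Palmul-tang and from 20.1 ± 0.793 to 11.45 ± 0.896 in Sibjeondaebo-tang. In the latter formulas the NF-kB list itself did not pass with an estimated correlation (adjusted p = 0.0514 and 0.346).

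The overlap of the dose steps asks whether Palmul-tang and Sibjeondaebo-tang moved the same genes, and these 2 contrasts share no library. Of the 258 genes that rose with Palmul-tang, 208 also rose with Sibjeondaebo-tang, against 47.75 for independent lists (Fisher's exact test, one-sided, p = 8.72e-106). Of the 357 that fell, 254 also fell, against 71.17 (Fisher's exact test, one-sided, p = 2.43e-99). Only 6 genes rose with Palmul-tang and fell with Sibjeondaebo-tang, and 3 did the opposite. These p-values treat genes as independent, which they are not. The shared total of 462 was 283 without Palmul-tang high replicate 1 and 282 without Palmul-tang low replicate 3. Over all 17701 genes the steps correlated at r = 0.167 across genes.

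At matched doses, Sibjeondaebo-tang and Palmul-tang were compared to ask how the formulas differed. Doses were matched by µg/mL of extract, and the content of each herb is not stated. The comparison therefore does not separate the added herbs from a different content of the shared ones. At the high dose 5360 genes differed, of which 2531 were higher and 2829 lower with Sibjeondaebo-tang. The direction with more genes depended on the processing, with 3128 higher and 2340 lower with no filter and 2404 and 2326 with DESeq2. It also turned without Sibjeondaebo-tang high replicate 1 (2267 and 2062), without Sibjeondaebo-tang high replicate 2 (2642 and 2165) and without Sibjeondaebo-tang high replicate 3 (2686 and 2306). The sizes were unequal: 459 genes were lower by 2-fold or more and 7 were higher by as much. At the medium dose edgeR called 0 genes, with 453 at an unadjusted p under 0.05, and DESeq2 called 1. At the low dose edgeR called 0, with 426 unadjusted, and DESeq2 called 0. The dose step itself differed between the formulas for 2634 genes, 989 with a higher and 1645 with a lower step in Sibjeondaebo-tang, but 1463 and 1473 with no filter on low counts.

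Among the largest falls at the high dose of Sibjeondaebo-tang against Palmul-tang, GOLGA8A (ENSG00000175265, chromosome 15, 34379068 to 34437466) stood at 11.8 ± 1.33 against 50.4 ± 10.3 CPM (n = 3 each), a log2 change of -2.09 (SE 0.16, adjusted p = 2.15e-08). Its copy GOLGA8B stood at 21.6 ± 1.37 against 72.2 ± 1.36 CPM and the pseudogene HERC2P2 at 33.0 ± 1.66 against 117 ± 9. These 3 belong to families of similar genes, and reads shared within a family are divided by the quantification. SEC31B (ENSG00000075826, chromosome 10, 100486642 to 100519864, which shares exons on the same strand with AL133352.1, so that reads are divided between them) stood at 2.50 ± 0.272 against 10.5 ± 1.90 CPM, CCDC18-AS1 (ENSG00000223745, chromosome 1, 93262186 to 93346025) at 1.23 ± 0.131 against 4.99 ± 0.815 and the long non-coding LINC00342 at 1.60 ± 0.159 against 5.20 ± 0.651. CCDC18-AS1 lies opposite the exons of CCDC18 and DR1, and the strand setting of the counting is not stated, so reads of those genes are not excluded from its counts. Of the 459 genes lower by 2-fold or more, 33.3% were long non-coding and 19.4% pseudogenes, against 13.5% and 5.7% of the tested genes, and 40.5% were protein-coding, against 78.8%. The median log2 difference was -0.26 over long non-coding genes, -0.20 over pseudogenes and 0.03 over protein-coding genes. Among list members, TRAF1 was lower with Sibjeondaebo-tang, at 3.69 ± 0.697 against 7.54 ± 0.413 CPM, as were CYP3A5, at 14.1 ± 1.02 against 25.9 ± 1.17, and CENPE, at 21.4 ± 0.388 against 35.2 ± 2.93. HMOX1 was higher, at 84.5 ± 4.86 against 67.3 ± 1.86 CPM (log2 change 0.33, SE 0.051, adjusted p = 1.01e-05), and SLC7A5 at 1517 ± 58.3 against 1208 ± 38.3. Among AhR targets CYP1B1 was higher by 0.14 log2 (SE 0.037, adjusted p = 0.00379), and the list did not pass (adjusted p = 0.573). Its member AHRR went the other way: it was lower and passed with edgeR, but not with DESeq2 (log2 change -0.382, adjusted p = 0.117). With the preset correlation 11 lists were higher with Sibjeondaebo-tang. They included the ribosomal protein, respiratory chain, cholesterol synthesis, lysosome and mitochondrial DNA-encoded mRNA lists. None of the 11 passed with an estimated correlation (adjusted p = 0.303 for the ribosomal protein list, 0.341 for the respiratory chain list and 0.612 for the mitochondrial DNA-encoded list, of whose 13 genes 1 passed as higher, also when adjusted over the list alone).

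**Figure D3:**
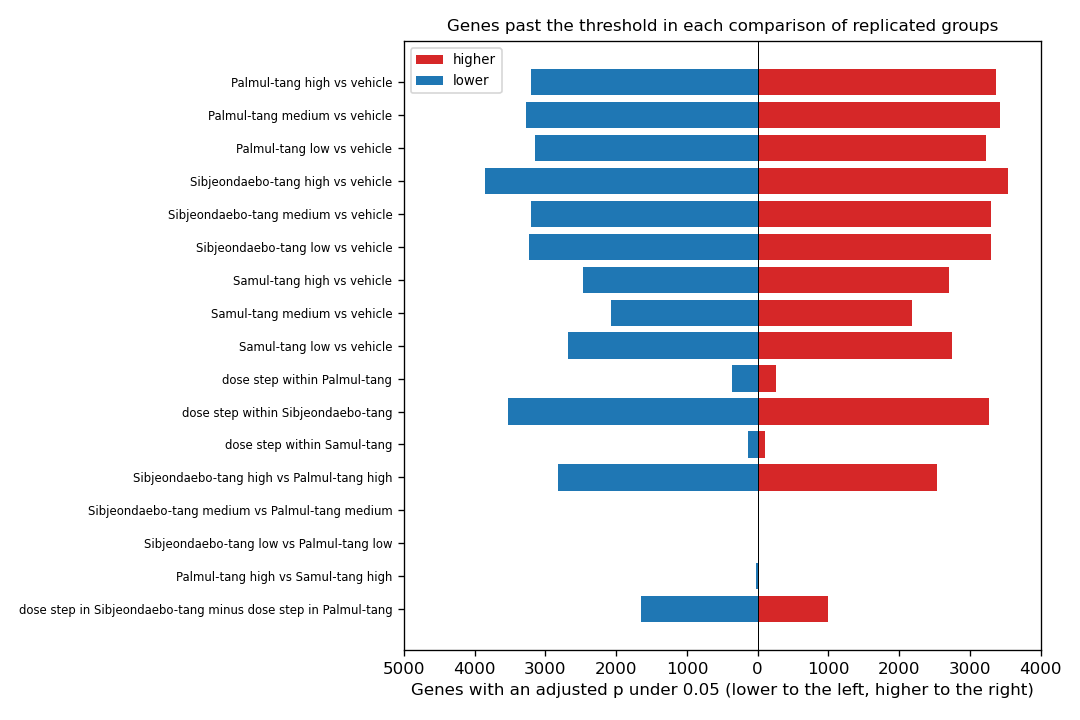
Bars give the number of genes with an adjusted p under 0.05 (horizontal) in each comparison of groups with at least 2 libraries, higher to the right in red and lower to the left in blue. The counts against vehicle are 6372 at the low dose of Palmul-tang and 6574 at its high dose, whereas the dose steps give 615 in Palmul-tang and 6805 in Sibjeondaebo-tang.

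Against the vehicle, many genes differed at every dose, most by small amounts. At the high dose of Sibjeondaebo-tang, however, 729 genes were lower and 45 higher by 2-fold or more, against 122 and 63 at that of Palmul-tang. With Palmul-tang 6574 genes differed at the high dose, 6700 at the medium and 6372 at the low dose, with a median size of 0.279, 0.281 and 0.279 log2 among those past the threshold. With Sibjeondaebo-tang the counts were 7395, 6508 and 6523 (median size 0.334, 0.275 and 0.285 log2). With Samul-tang they were 5166, 4250 and 5430, which became 2769 without Samul-tang high replicate 3, 2462 without Samul-tang medium replicate 2, 2400 without Samul-tang medium replicate 3 and 2410 without Samul-tang low replicate 3. At the high dose of Palmul-tang 3366 were up and 3208 down (2755 and 2796 with only the groups compared in the fit). At that of Sibjeondaebo-tang 3543 were up and 3852 down, against 3834 and 3309 with no filter and 3322 and 3234 with DESeq2. That majority also turned without Sibjeondaebo-tang high replicate 1 (3341 and 3013), without Sibjeondaebo-tang high replicate 2 (3538 and 3115) and without Sibjeondaebo-tang high replicate 3 (3498 and 3230). The 3 vehicle libraries enter each of these comparisons, so the counts are not independent of each other.

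At the high dose of Palmul-tang the largest falls against vehicle included non-coding RNAs. RN7SL1 stood at 9.18 ± 1.76 against 25.0 ± 5.76 CPM and the long non-coding FP236383.3 at 251 ± 80.1 against 1170 ± 25.4. Among genes that met the naming rule CXCR5 had the largest fitted fall, at 1.57 ± 2.72 against 27.2 ± 9.94 CPM. CXCR5 overlaps exons of BCL9L on the other strand and did not pass with DESeq2 (adjusted p = 0.248), without Palmul-tang high replicate 1 (0.0619) or without Palmul-tang high replicate 3 (0.0577). Its fall was not particular to the high dose. The DESeq2 log2 change against vehicle was -3.70 at the low, -3.74 at the medium and -4.11 at the high dose of Palmul-tang. GRHL3, at 6.49 ± 0.958 against 3.48 ± 0.302 CPM, and PPM1E, at 5.39 ± 0.598 against 2.91 ± 0.338, were among the largest rises. CYP1B1 stood at 207 ± 3.01 against 114 ± 2.14 CPM in the vehicle (log2 change 0.86, SE 0.038, adjusted p = 3.99e-17), and at 228 ± 9.25 with Sibjeondaebo-tang (1.00) and 182 ± 0.473 with Samul-tang (0.67). The AhR and NRF2 lists passed with an estimated correlation against vehicle at the high dose of all 3 replicated formulas, at adjusted p = 0.000192 and 0.0438 with Palmul-tang, 0.000573 and 0.0102 with Sibjeondaebo-tang and 0.00231 and 0.0488 with Samul-tang. Fatty acid oxidation and PPAR targets passed with Palmul-tang (0.0331) and Samul-tang (0.0107) but not with Sibjeondaebo-tang (0.0556), and a difference between formulas in that list was not tested. That list did not pass in the dose step of Palmul-tang or of Sibjeondaebo-tang with either correlation. In Palmul-tang its result therefore rests on the comparison with vehicle. Of its 13 tested genes 9 rose with Palmul-tang (9 adjusted over the list alone), PDK4 from 345 ± 4.39 to 442 ± 13.9 CPM. Cholesterol synthesis genes fell with Palmul-tang, 12 down and 2 up of 24 (the same counts adjusted over the list alone), but the list did not pass with an estimated correlation (adjusted p = 0.13). At the medium and low doses 0 lists passed with an estimated correlation in any of the 4 formulas, against 2 to 9 with the preset one.

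Palmul-tang and Samul-tang at the high dose differed in 34 genes, 10 higher and 24 lower with Palmul-tang (31 and 33 with the replicate block, 46 and 84 with no filter, 18 and 51 with DESeq2, 8 and 11 with only the groups compared in the fit). That count was 8 without Samul-tang high replicate 2 (4 and 4), 6 without Samul-tang high replicate 3, 21 without Palmul-tang high replicate 1 and 19 without Palmul-tang high replicate 3. The titles give both formulas the same batch, but their library codes begin with different numbers, whose meaning is not stated. The hypoxia and glycolysis list was lower with Palmul-tang, with 5 of 23 genes past the threshold (14 adjusted over the list alone, list adjusted p = 0.00809 with an estimated correlation). The AhR list was higher, with 2 of 9 (5 up and 1 down adjusted over the list alone, 0.0227). List tests of these formulas against each other were not planned beforehand and were not repeated without single libraries. STC1 and ID2, chosen after the values were seen, stood at 23.8 ± 0.601 and 13.7 ± 0.960 CPM with Palmul-tang against 37.3 ± 1.38 and 19.7 ± 0.189 with Samul-tang.

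Sagunja-tang had 1 library per dose, so the test assumes that it varies like the other groups. On that assumption 2448 genes differed from vehicle at the high dose, 2549 at the medium and 3389 at the low dose. Without vehicle replicate 1 the first count was 1428 and the second 1475. With only the groups compared in the fit the counts were 1182, 1335 and 2143, and at the high dose the majority turned from 1317 up and 1131 down to 506 up and 676 down. The high-dose library held 260 CPM of CYP1B1, 125 of AQP3 and 13.5 of CYP1A1, each above every library of the other formulas at that dose, and 59.4 of HMOX1, below the high-dose means of the others. NR4A1 stood at 8.57 CPM against 18.3 ± 1.36 in the vehicle. A dose response within Sagunja-tang was not assessed, because variation between libraries cannot be separated from dose with 1 library each.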

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

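The tests of library batch, of depth and of the read density on nearly silent receptor genes were chosen only after the results they bear on were seen. A difference between groups drew attention to the dose step, which differed between Sibjeondaebo-tang and Palmul-tang for 2634 genes, 989 with a higher and 1645 with a lower step in Sibjeondaebo-tang. The excess of lower steps was absent with no filter on low counts, at 1463 higher and 1473 lower. With DESeq2 the count was 2383, at 1060 and 1323, and without 1 library in turn it ran from 1893 to 2850. Of 100 drawn splits of the formulas within each dose, 9 gave as many genes, the real one included, with 3763 as the highest other, so chance is not excluded by this count. Each of those 9 kept the real formula labels at the high dose, and draws that did not keep them gave at most 2 genes. Splits that keep those labels point to a structure of the samples, the difference between the high-dose libraries. They retain that difference, so they cannot test chance.

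The fall of transcripts at the high dose of Sibjeondaebo-tang was weighed as a pattern. Against Palmul-tang at the same dose 459 genes were lower by 2-fold or more and 7 were higher by as much. The 3 high-dose libraries of Sibjeondaebo-tang also held a count for the fewest genes, 21754, 21934 and 22283, against 22412 or more in the other 27. Transcripts of mitochondrial DNA made up 15.3 ± 0.701% of their counts, against 12.8 ± 1.29% at the low dose and 13.9 ± 1.54% at the high dose of Palmul-tang, but 15.8 ± 0.0726% at the high dose of Samul-tang. Gene length and GC content were argued against: after each library was corrected for both, 411 of the 448 genes with known length and GC were still lower by 2-fold or more, with a median log2 change of -1.31 before and after. Reads from genomic DNA were argued against as the main source. Counts on 835 nearly silent olfactory receptor genes were lower in these libraries, at 0.793 ± 0.062 against 1.44 ± 0.261 CPM with Palmul-tang (ratio 0.551, no overlap), which goes with less background there. The density lost on these genes nevertheless gave 0.164% of the fall of the median gene and 3.16% at the highest. An earlier form of that test, a ratio of 1.013 over all 841 receptor genes, was void because 6 genes held 92.2% of the receptor counts. Incompletely spliced transcripts remained open. Of 186 protein-coding genes in the fall, 62.9% had an annotated retained-intron isoform, against a median of 55.4% and a 95th percentile of 59.7% in 10000 matched lists. A share above that percentile had been set beforehand as going with this explanation. An annotated isoform does not measure splicing in these libraries. The genes in the fall, of all classes, had a median of 5 intron blocks against 8 over all tested genes, and of 9504.5 bases of span against 24837. This was not compared within a class. The fall held larger shares of long non-coding genes and pseudogenes than the tested genes, so the comparison argues neither way. A lower share of nuclear or incompletely spliced RNA in these 3 libraries may be part of the pattern, but was not measured directly. Whether it arose in the cells through the extract or in the preparation of the RNA cannot be settled from these libraries, and a biological response stays open and untested.

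The vehicle libraries stood apart from every extract dose, with 6372 genes between vehicle and the low dose of Palmul-tang. A response that keeps growing with dose was argued against: over those genes the signed median change from the medium to the high dose was -0.018 log2, against a median size of 0.279 at the low dose. Over the low-dose genes of the other formulas it was 0.004 in Samul-tang (median size 0.288) and -0.085 in Sibjeondaebo-tang (0.285). In Sibjeondaebo-tang 2101 of these genes passed from the medium to the high dose in the other direction and 646 in the same. The high dose there moved such genes partly back toward vehicle, in the median. A difference in depth was argued against, since 5806 genes still passed when every library was thinned to the smallest total. The titles give all 30 libraries the same batch, so no batch named in the labels separates vehicle from extract. A library batch that the titles do not name cannot be told apart from the treatment, because no extract library shares the prefix of the vehicle's library codes, and what the prefixes stand for is not stated. Short non-coding RNAs, whose recovery could vary with library preparation, had a median change of -0.88 over 18 genes, of which 9 passed as lower and 0 as higher by edgeR. At the low dose the median was -1.11 in Sibjeondaebo-tang, -0.80 in Samul-tang and -0.915 in the single library of Sagunja-tang. At the high dose it was -1.04 in Palmul-tang, -0.82 in Sibjeondaebo-tang, -0.65 in Samul-tang and -0.115 in the single library of Sagunja-tang, and differences between these groups were not tested. A response already complete at the lowest dose stays open as a biological explanation. The labels give a DMSO content for the vehicle libraries only. Whether the solvent also differed between vehicle and extract is therefore not known.

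Other splits of the libraries were counted where both groups had 3. Each such comparison has 10 splits, which are too few for a share under 0.05. The real count of genes and the highest other were 6574 and 7 for the high dose of Palmul-tang against vehicle, 6700 and 0 for its medium dose and 6372 and 0 for its low dose. They were 7395 and 0, 6508 and 0, and 6523 and 0 for the same doses of Sibjeondaebo-tang. They were 615 and 0 for the dose step of Palmul-tang, 6805 and 0 for that of Sibjeondaebo-tang, and 5360 and 1 for the high doses compared. In each of these 1 of 10 splits gave as many genes, the real one. For the medium and low doses of both formulas the real count was 0 by edgeR (453 and 426 at an unadjusted p under 0.05, and 1 and 0 by DESeq2), so 10 of 10 splits gave as many, with 0 and 27 as the highest other. For lists the real and highest other counts were 11 and 13 for the high dose of Palmul-tang (3 of 10 splits as many), 12 and 11 for that of Sibjeondaebo-tang, 17 and 15 for the dose step of Palmul-tang, 12 and 10 for that of Sibjeondaebo-tang, and 11 and 12 for the high doses compared (2 of 10). The overlap of 462 genes between the dose steps was reached in 1 of 100 pairs of splits, the real one, with 0 as the highest other. Since no other split of either dose step called a gene, no other pair had genes to share, so this count says nothing about the overlap beyond the counts of each dose step.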

How the results depend on the processing

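The low dose as reference, the thinned counts and the fits without the vehicle or the high dose of Sibjeondaebo-tang were chosen only after the data were seen. Totals are compared here, and the direction with more genes turned in several comparisons. For the dose step of Sibjeondaebo-tang and for Sibjeondaebo-tang against Palmul-tang at the high dose it turned with no filter, with DESeq2 and without any 1 of the 3 high-dose libraries of Sibjeondaebo-tang, as the report gives, and the cause was not tested. With RLE size factors, thinned counts, and the fits without vehicle or without the high dose of Sibjeondaebo-tang, each count that could be computed stayed within 1.5 times its value.

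With no filter on low counts the dose step of Samul-tang gave 464 genes, Palmul-tang against Samul-tang 130, and Sibjeondaebo-tang against Palmul-tang 2 at the medium and 1 at the low dose. With the replicate block the dose step of Samul-tang gave 373 and Palmul-tang against Samul-tang 64. With DESeq2 Palmul-tang against Samul-tang gave 69 and Sibjeondaebo-tang against Palmul-tang at the medium dose 1. The cause was not tested. With only the groups compared in the fit, which changes both the libraries behind the spread and the genes that pass the filter, Sagunja-tang gave 1182, 1335 and 2143 genes at the high, medium and low dose, the dose steps of Palmul-tang and Samul-tang 381 and 488, and Palmul-tang against Samul-tang 19. The cause was not tested.

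With the low dose of each formula as the reference in place of vehicle, Palmul-tang gave 615 genes at the high and 1 at the medium dose, Sibjeondaebo-tang 2 at the medium dose, Samul-tang 238 and 0, and Sagunja-tang 174 and 0, which compare single libraries and do not separate dose from variation between libraries (988 and 489 at an unadjusted p under 0.05 for the counts of 0 by edgeR). By construction this leaves out any difference between vehicle and all extracts. With the estimated correlation, which widens the list test, the lists fell to 3, 2 and 5 for the high doses of Palmul-tang, Sibjeondaebo-tang and Samul-tang against vehicle, 9 and 3 for the dose steps of Palmul-tang and Sibjeondaebo-tang, and 0 for the high doses compared (11 with the preset correlation).

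Leaving out each library in turn, where a lone library is assumed to vary like the other groups, gave 2769 to 5015 genes for Samul-tang high, 2400 to 4229 for medium and 2410 to 5458 for low. It gave 1428 to 2662 for Sagunja-tang high and 1475 to 2821 for medium, 49 to 149 for the dose step of Samul-tang, 351 to 591 for that of Palmul-tang, 6 to 38 for Palmul-tang against Samul-tang, and 282 to 482 for the overlap. Other ranges were 6083 to 6978 for Sibjeondaebo-tang high, 5739 to 6408 for its dose step and 4149 to 4999 for the high doses compared. The named genes were chosen because they passed in these same data, so reversals were unlikely in advance. Of 9316 alternative values of the named genes, 8805 kept direction and side of the threshold, 511 no longer passed and 0 reversed. That count leaves out the low dose as reference, under which 133 of 370 values kept direction and side, 174 no longer passed and 63 took the other direction, 1 of them past the threshold. Depth limited little: thinned to 23986616 counts per library, the low dose of Palmul-tang gave 5806 genes.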
